A study of Mus musculus with 2 samples.

How the data were processed

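The data are processed files of 2 polyA RNA-seq libraries from adult mouse tissue labelled large intestine, as stranded paired reads of 76 nt from RNA longer than 200 nt, per the labels. The authors deposited a gene table and a transcript table for each library, on build mm10 with the GENCODE M4 annotation per the accompanying notes. The aligner, the quantification program and their versions are not given in the sources used here. The tables hold expected counts, which the authors estimated per gene and per transcript and which need not be whole. The deposited TPM values have the same total in each library over all features, spike-ins included, with a correction for effective length. The deposited FPKM values were used only as an alternative. Each transcript's percent of its gene's TPM was used as deposited. Maximum likelihood values were the main ones, and the posterior mean values of the same tables an alternative. Bounds on TPM are deposited as a further signal column and were not printed.

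A junction list and a contig list of the whole series were deposited on build mm9. The read counts per junction are deposited as whole numbers, equal for all 446811 junctions to the sum of 2 read count fields in the junction's name. Which replicate each field stands for is not stated in the sources used here, so the fields were not assigned to samples. The contig level is a deposited signal that the authors normalized to depth, and the reproducibility value is a deposited score whose definition is not given in the sources used here. Positions are printed with 1-based starts, and mm9 and mm10 positions were never combined.

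The gene tables hold 69691 features: 43346 genes, 97 spike-in or control sequences and 26248 entries with numeric identifiers, all at 0 counts. Symbols, biotypes and mm10 positions came from GENCODE M21, matched on the gene identifier without its version, and 42462 genes had a symbol. Of the 458 list entries 456 were matched. TPM was not changed in the main results. Genes were called detected at 1 TPM or more in both libraries. Ratios between the libraries were log2((TPM + 1) of replicate 2 / (TPM + 1) of replicate 1), which understates the difference of low genes, over genes with a mean TPM of at least 1. Since each comparison sets 1 library against 1, no p-value was computed. The 2 libraries were compared by chi-square per gene over 17110 genes with at least 20 counts in all, to check that they were not 1 library deposited under 2 names.

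The gene lists, 50 in number, and the rule for named genes were fixed before the data were examined. The rule took the 20 genes with the highest mean TPM outside the mitochondrial genome and spike-ins, and the 3 highest members of each list. It also took list members below 1 TPM in background and positional lists, the 10 genes with the largest ratio in each direction at a mean TPM of at least 10, a fixed set of isoform genes, and the 5 junctions and contigs with the highest support. The text names some of these and gives others as counts. Further members of the fixed lists were named after their values were seen: Car1, Aqp8, Atp12a, Slc9a3, Scnn1a, Scnn1b, Scnn1g, Aqp3, Sis, Lct, Nr1h4, Fgf15, Cyp3a11, Cdx2, Gata4, Insl5, Lgr5, Trpm5, Adipoq, Xist, Egr1, Usp18 and Gkn2. For each list with at least 4 members at a mean TPM of 1, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these libraries only. A gene at 0 counts was set to a floor of 3 counts for a bound on its fold.

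Depth was 50189619 and 58233142 expected counts. Both steps were tested on simulated data drawn from the 13512 genes and the real library sizes. In the replicate difference step, 82 of 100 genes changed 2.5-fold and 97 of 100 changed 4-fold were over 2-fold apart, as were 0 of 13312 unchanged genes. In the list step a simulated shift of 0.8 in 1 list came back as 0.91, and 7 of 200 unshifted lists fell outside the central 95% of their random lists. The simulated genes varied independently of each other, all with the same preset spread between libraries. These rates therefore test the steps and are not the error rates of the real libraries.

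Alternatives were other minimums, pseudocounts and filters, FPKM, posterior means, TPM rescaled without mitochondrial genes and spike-ins, shares of expected counts, and leaving out each library. Expected counts, rounded to whole numbers, were also scaled with TMM (edgeR 4.0.16) and with median-ratio size factors (DESeq2 1.42.0) in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alignments and the signal tracks of the series were not used here.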

Results

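PolyA-selected RNA was sequenced from tissue of adult C57BL/6J mice, an inbred laboratory strain, at 8 weeks of age. The labels describe 1 group, large intestine, with 2 biological replicates, each said to pool male and female littermates. Both replicates are recorded as separate biosamples under a single donor record. Expected counts came to 50189619 in the replicate 1 library and 58233142 in the replicate 2 library, of which 48724618 and 55655330 fell on annotated genes. With 1 group the design holds no comparison between conditions, so the values below describe the transcripts present in the tissue and how far the libraries lay apart. A difference between the libraries is 1 library against 1 and has no replicate check. Errors are the SD over both libraries (n = 2), and bounds or floors on counts and folds cover counting error only.

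Both libraries labelled large intestine held high levels of transcripts typical of Paneth cells and of small intestine enterocytes, lists that had been fixed as background. The 7 genes of the Paneth list summed to 18207 TPM ± 7295 (SD, n = 2), and all of them lay above 10 TPM in both libraries. The 10 genes of the small intestine enterocyte list summed to 5376 TPM ± 1379 (SD, n = 2), and all were detected at 1 TPM or more in both. Lyz1, the Paneth cell lysozyme (ENSMUSG00000069515.5, chromosome 10, 117287797 to 117292868, mm10), reached 4597 TPM in replicate 1 and 6826 TPM in replicate 2. Sis, which encodes sucrase-isomaltase, a brush border disaccharidase, was at 281 TPM in replicate 1 and 79.7 TPM in replicate 2.

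The colonocyte list was split. Of its 11 genes, 7 were detected in both libraries and 3 lay below 1 TPM in both. Guca2a, the gene of the peptide guanylin, was the highest member at 1303 TPM ± 147 (SD, n = 2), followed by Krt20 at 518 ± 258 TPM and Car4 at 129 ± 16.9 TPM, genes that are not restricted to the colon. Car1, which encodes a carbonic anhydrase abundant in colon epithelium (ENSMUSG00000027556.11, chromosome 3, 14766216 to 14808368), was at 0.23 TPM in replicate 1 from 10 expected counts and 0.27 TPM in replicate 2 from 15. The water channel gene Aqp8 was at 0.04 TPM and the proton pump gene Atp12a at 0.01 TPM in each library. In the ion and water transport list, the epithelial sodium channel subunit gene Scnn1g had 0 counts in both libraries and Scnn1b had 2 and 0. Scnn1a, the subunit gene with wider expression, was at 7.3 TPM ± 1.16 (SD, n = 2). These levels go against the tissue label, which is therefore given here as a label. No other tissue and no separate segment of the large intestine was compared.

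**Figure D1:**
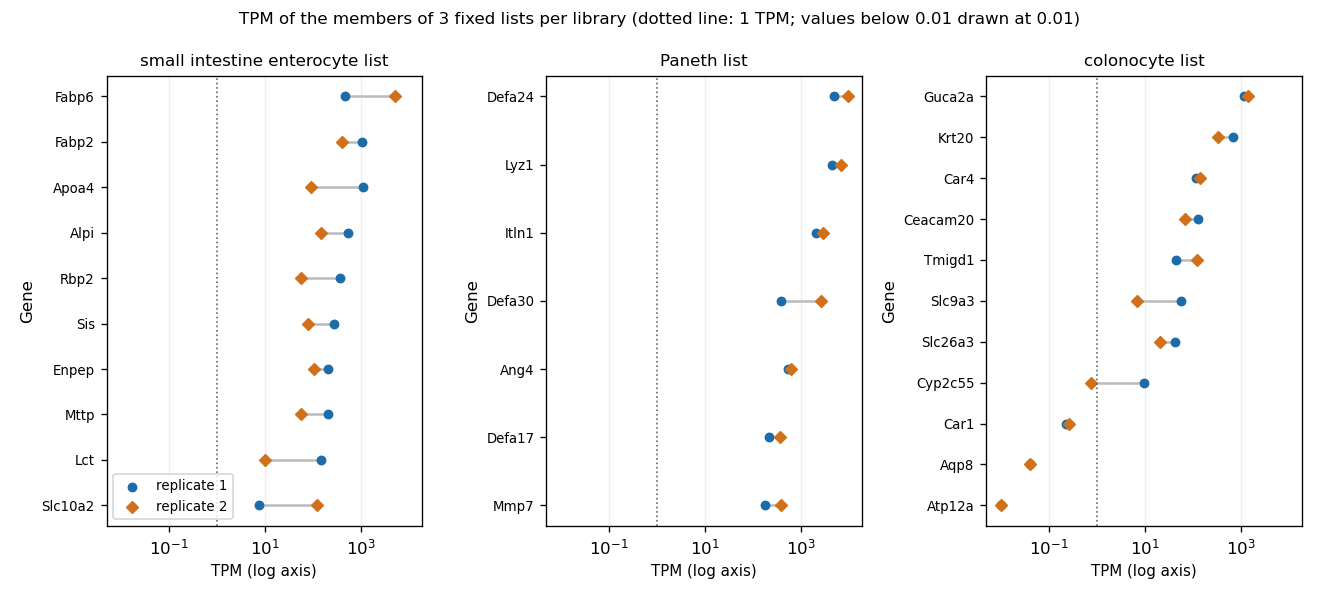
TPM on a log axis of every member of the small intestine enterocyte, Paneth and colonocyte lists in the replicate 1 library (circles) and the replicate 2 library (diamonds), with a grey line joining both. All members of the first 2 lists lie to the right of the dotted line at 1 TPM, whereas Car1, Aqp8 and Atp12a of the colonocyte list lie to its left in both libraries.

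Hox genes, whose position in the clusters follows the body axis, were mostly low. The 15 anterior Hox genes (paralog groups 1 to 5) summed to 20.6 TPM ± 0.976 (SD, n = 2). The 16 posterior Hox genes (groups 9 to 13) summed to 0.59 TPM in replicate 1 and 14.1 TPM in replicate 2, and 15 of them lay below 1 TPM in both libraries. The posterior to anterior ratio was 0.0297 in replicate 1 and 0.662 in replicate 2. The higher value rested on Hoxb9 (ENSMUSG00000020875.9, chromosome 11, 96271457 to 96276595), with 17 expected counts (0.19 TPM) in replicate 1 and 1609 (13.1 TPM) in replicate 2, and without the most abundant member of each list the mean ratio was 0.0390. Hoxa13 and Hoxd13, expressed at the posterior end of the gut, had 0 counts in both. Among regional transcription factors, Hnf4a was at 311 TPM ± 56.8 (SD, n = 2), Cdx1 at 229 ± 54.9 and Cdx2 at 133 ± 14.8. Gata4, a factor of the proximal small intestine, was at 52.9 TPM in replicate 1 and 7.45 TPM in replicate 2.

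Reg3b, Igkc and Sprr2a2 had the highest mean TPM of all genes outside the mitochondrial genome. Reg3b, which encodes a C-type lectin, was at 15225 TPM in replicate 1 and 43967 TPM in replicate 2. The antibody light chain constant gene Igkc followed at 28352 TPM ± 10277 (SD, n = 2), and Sprr2a2 at 19725 ± 162 TPM. Noncoding RNAs were also among the 20 highest, such as Rn7sk at 12103 and 6674 TPM and Gm42418 at 6507 and 5604 TPM. The nuclear noncoding list, fixed to look at RNA selection and quality, summed to 14991 TPM in replicate 1 and 8391 TPM in replicate 2. What these levels mean for the polyA selection given in the labels was not tested. The 14 genes of the antimicrobial defence list took 3.85% of all TPM in replicate 1 and 8.66% in replicate 2, and Reg3g was at 5754 and 20357 TPM. All 11 goblet cell genes were detected in both libraries, led by Spink4 at 13206 TPM ± 668 (SD, n = 2) and Tff3 at 11661 ± 3683 TPM. The gel-forming mucin gene Muc2 was at 1895 ± 148 TPM, and the membrane mucin gene Muc13 at 1445 ± 163 TPM. The 100 most abundant genes held 44.6% ± 2.79 (SD, n = 2) of the TPM, and the 13 mitochondrial protein-coding genes 6.27% in replicate 1 and 3.05% in replicate 2. The most abundant of these by TPM was mt-Atp8, at 22127 TPM from 3663 expected counts in replicate 1, a short gene for which the length correction is large.

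**Figure D2:**
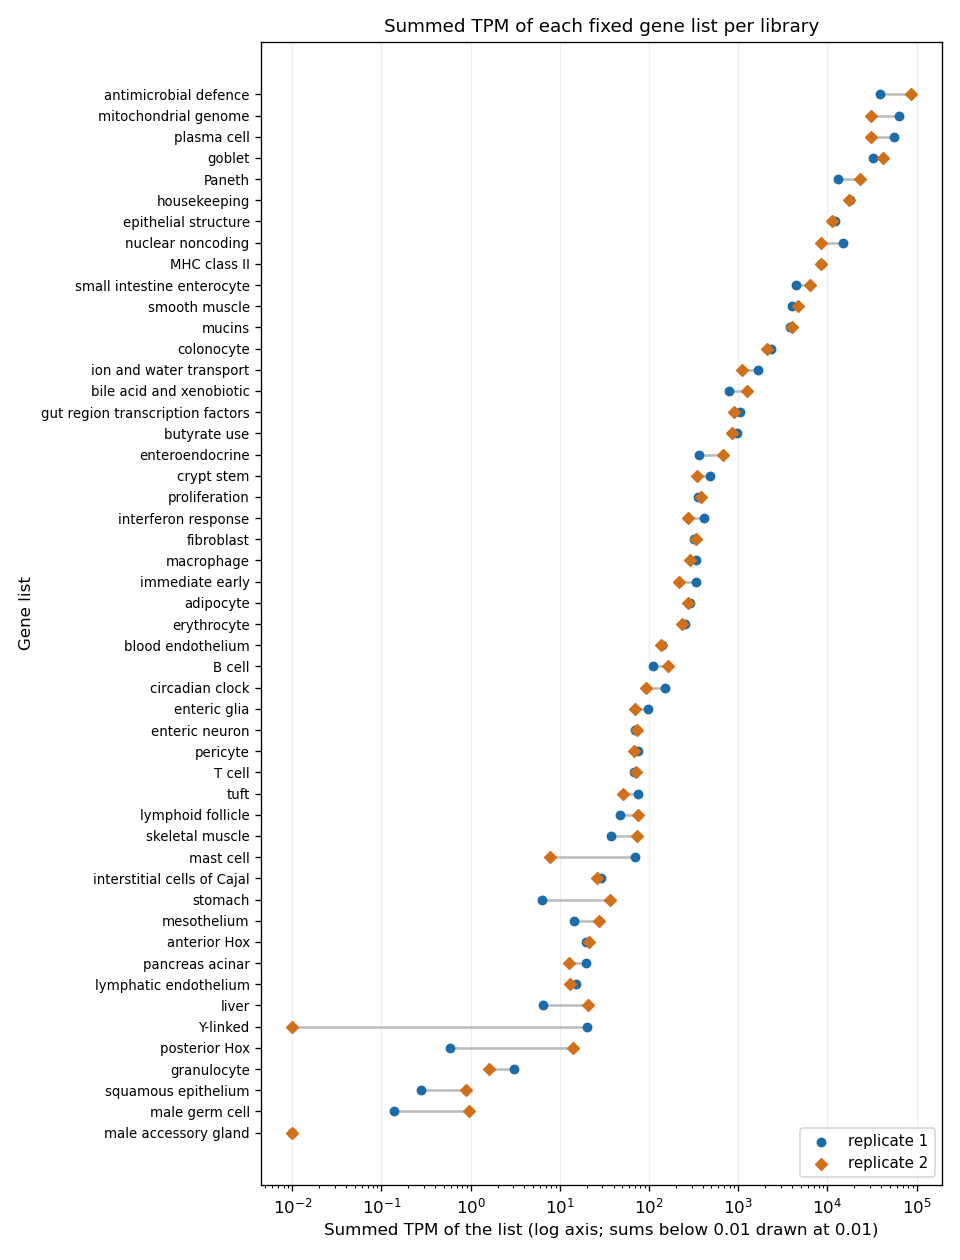
Summed TPM on a log axis of each of the 50 fixed gene lists in the replicate 1 library (circles) and the replicate 2 library (diamonds). The antimicrobial defence, mitochondrial genome, plasma cell, goblet and Paneth lists have the highest mean sums, and the male accessory gland list is at 0 in both libraries, drawn at 0.01.

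Genes of muscle, connective tissue, nerve and vessels were detected beside those of the epithelium. The 12 smooth muscle genes summed to 4368 TPM ± 517 (SD, n = 2), with Acta2 at 1266 ± 208 TPM and the gut-enriched actin gene Actg2 at 1020 ± 57.9 TPM. Their sum was 0.374 ± 0.0668 (SD, n = 2) of that of the 10 epithelial structure genes, which reached 11741 TPM ± 715 and were led by Lgals4 at 3460 ± 212 TPM. Fibroblast genes summed to 328 TPM ± 8.46 (SD, n = 2), with Dcn at 138 ± 16.7 TPM. All 4 genes of the interstitial cells of Cajal list, the pacemaker cells of gut muscle, were detected, among them Kit at 9.4 TPM ± 0.0707 (SD, n = 2). Of the 13 enteric neuron genes 9 were detected in both libraries, led by Vip at 26.8 TPM ± 5.92 (SD, n = 2). The enteric glia list was dominated by Erbb3 at 76.7 TPM, which epithelium also expresses, while Sox10 was at 1.85 TPM. Blood endothelium summed to 137 TPM ± 3.27 (SD, n = 2), pericytes to 71.6 ± 5.32 TPM and lymphatic endothelium to 14.2 ± 1.48 TPM.

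Epithelial cell types beyond absorptive and goblet cells were detected in both libraries. All 11 crypt stem genes were present, with Olfm4 at 239 TPM ± 79.5 (SD, n = 2) and Lgr5 at 4.28 ± 0.573 TPM, as were all 13 proliferation genes, led by Pcna at 79.8 ± 1.83 TPM. The enteroendocrine list was led by the hormone gene Pyy, at 169 TPM in replicate 1 and 437 TPM in replicate 2. Insl5, a hormone gene of distal colon endocrine cells, was at 0.2 and 1.08 TPM. The tuft cell list had 6 of 10 genes detected in both libraries, with Trpm5 at 7.61 TPM ± 3.25 (SD, n = 2).

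Plasma cell transcripts outweighed those of other immune cells. The 7 plasma cell genes summed to 43165 TPM ± 17139 (SD, n = 2), with the IgA heavy chain gene Igha (ENSMUSG00000095079.2, chromosome 12, 113254830 to 113260236) at 17969 TPM in replicate 1 and 8967 TPM in replicate 2 and Jchain at 1479 and 778 TPM. The 6 MHC class II genes summed to 8441 TPM ± 46.1 (SD, n = 2). Macrophage genes summed to 311 TPM ± 30.9, B cell genes to 137 ± 36.0 TPM and T cell genes to 70.03 ± 1.99 TPM. No granulocyte gene of the 8 listed reached 1 TPM in either library. Erythrocyte genes summed to 244 TPM ± 16.1 (SD, n = 2).

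Of the other background lists, squamous epithelium (0.585 TPM ± 0.431), male germ cell (0.555 ± 0.587 TPM) and male accessory gland (0 TPM in both) had no member at 1 TPM in either library. Pancreas acinar genes summed to 16.3 TPM ± 5.09 (SD, n = 2), liver genes to 13.7 ± 10.05 TPM and skeletal muscle genes to 55.95 ± 25.5 TPM, the last mostly from Ckm at 35.7 ± 8.14 TPM. Adipocyte genes summed to 278 TPM ± 10.4 (SD, n = 2), with Adipoq at 22.1 ± 0.658 TPM.

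In all, 12949 genes were detected at 1 TPM or more in both libraries, 93.2% of them protein-coding, and 972 reached this level in 1 library. Across the 13512 genes with a mean TPM of at least 1, log2(TPM + 1) had a Pearson correlation of 0.952 between the libraries and a Spearman correlation of 0.955. These are correlations across genes, which are not independent replicates. The libraries were not copies of each other: 65.4% of 17110 genes differed beyond the 95% limit of counting error, where 5% would by chance. Of the 13512 genes, 762 (5.64%) differed at least 2-fold on the log2(TPM + 1) scale, 603 higher in replicate 1 and 159 higher in replicate 2. The median log2 ratio of replicate 2 over replicate 1 over all these genes was -0.14, and single-gene ratios are to be read against it. With expected counts scaled by TMM, the median was 0.01 and 513 genes differed at least 2-fold, 356 and 157 in each direction.

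Small intestine enterocyte genes differed in both directions between the libraries. Fabp6, the ileal bile acid binding protein gene (ENSMUSG00000020405.4, chromosome 11, 43596049 to 43601540), was at 477 TPM in replicate 1 and 5279 TPM in replicate 2, and the ileal bile acid transporter gene Slc10a2 at 7.62 and 125 TPM. The other 8 members were all higher in replicate 1, by a median log2 ratio of -1.86. Among them, the lactase gene Lct (ENSMUSG00000026354.8, chromosome 1, 128284756 to 128328318) was at 152 TPM in replicate 1 and 9.94 TPM in replicate 2, and the apolipoprotein gene Apoa4 at 1094 and 91.1 TPM. The list's median log2 ratio was -1.81, at percentile 0 among 10000 random lists matched on mean expression. In the bile acid and xenobiotic list 8 of 11 genes were higher in replicate 2, including the bile acid receptor gene Nr1h4 at 33.7 and 57.4 TPM and the hormone gene Fgf15 at 4.5 and 18.7 TPM. Cyp3a11 was lower there, at 16.1 TPM in replicate 1 and 0.72 TPM in replicate 2. The sodium-proton exchanger gene Slc9a3 was at 57.6 and 6.89 TPM, and the water channel gene Aqp3 at 39.97 and 4.9 TPM.

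Of the 41 lists with at least 4 measured members, 20 lay outside the central 95% of their random lists, 9 below and 11 above. For lists of independently drawn genes 2.05 would. Members of 1 list can vary together and some lists share genes, so this contrast is a description and not a test. Lists higher in replicate 2 included Paneth (median log2 ratio 0.76, percentile 100), goblet (0.23, percentile 99.5), B cell (0.54, percentile 100) and enteroendocrine (0.38, percentile 100). Lists higher in replicate 1 included mitochondrial genome (-1.05, percentile 0), colonocyte (-0.96, percentile 0.01) and plasma cell (-0.89, percentile 0.06). With no filter on low values, which adds Car1, Aqp8 and Atp12a, the colonocyte median was 0 at percentile 74.3. Housekeeping genes were at percentile 44.1 and MHC class II genes at 58.4. Epithelial structure genes, at -0.14, and MHC class II genes, at -0.04, changed sign under count-based scaling, to 0.03 and 0.14 with TMM.

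**Figure D3:**
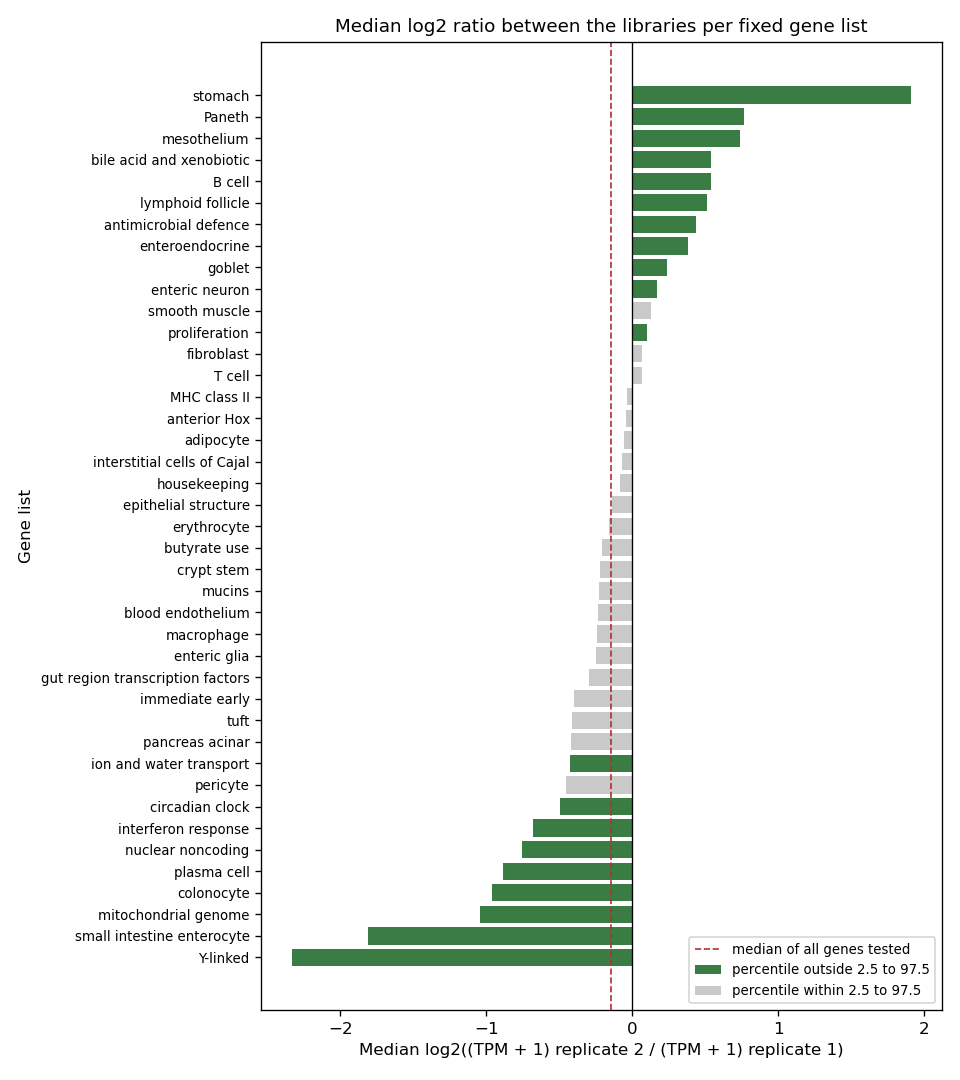
Median log2 ratio of replicate 2 over replicate 1, with a pseudocount of 1 TPM, for each of the 41 lists with at least 4 members at a mean TPM of 1 or more. Green bars mark lists outside the central 95% of 10000 matched random lists, grey bars the rest, and the dashed line the median of all genes, -0.14; the stomach list is highest at 1.91 and the Y-linked list lowest at -2.33.

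The alpha-defensin genes, a tandem family on chromosome 8 whose members are nearly identical, led the genes higher in replicate 2. The 22 genes named Defa and a number summed to 17604 TPM in replicate 1 and 85242 TPM in replicate 2. This sum leaves out Gm7861 and Gm14851, which lie in the same stretch of chromosome 8. They were at 0 and 8.29 TPM in replicate 1 and at 5985 and 2133 TPM in replicate 2. Defa21, Defa20 and Defa32 had 0 expected counts in replicate 1 and 9814, 7228 and 4552 TPM in replicate 2, for Defa21 at least 29824-fold above the floor of 3 counts. Defa33 had 1 expected count in replicate 1 and 208726 in replicate 2. Other members were present in both, such as Defa24 at 5012 and 9564 TPM and Defa3 at 7562 and 5504 TPM, and Defa35 was higher in replicate 1, at 608 and 14.7 TPM. Values of single members are uncertain, since reads can be split between such copies, and what sets the members apart was not tested. Outside this family, Saa1, an acute phase protein gene, was at 3.22 TPM in replicate 1 and 355 TPM in replicate 2.

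Antibody variable genes differed more than other genes. Of 163 such genes with a mean TPM of at least 1, 97 (59.5%) differed at least 2-fold, against 4.98% of the other 13349 genes. Of the 97, 75 were higher in replicate 1, a share close to that of all genes at least 2-fold apart (603 of 762). Igkv3-1 was at 236 TPM in replicate 1 and 3.07 TPM in replicate 2, whereas Ighv1-31 was at 1.38 and 212 TPM. These genes also share sequence within their families. The largest ratio in favour of replicate 1, that of the pseudogene Gm12338, came from 75.6 expected counts in replicate 1 against 124 in replicate 2, so that its counts and its TPM of 1556 and 0 went in opposite directions.

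Y-linked and Xist transcripts were each abundant in a different library. The 4 Y-linked genes held 2741 expected counts in replicate 1 and 3 in replicate 2, among them Kdm5d (ENSMUSG00000056673.10, chromosome Y, 897788 to 956786) with 1290 and 1. Xist, the noncoding RNA of the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 17 expected counts (0.02 TPM) in replicate 1 and 12563 (20.4 TPM) in replicate 2. These counts go against the label that each replicate pools both sexes.

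The pyruvate kinase, myosin kinase and Hnf4a genes were each mostly 1 transcript in both libraries. Among 6751 genes with at least 2 annotated transcripts and a mean of at least 5 TPM, 1558 (23.1%) had the same transcript at 90% or more of the gene in both libraries. The most abundant transcript was the same in both libraries for 5959 genes (88.3%). For the myosin kinase gene Mylk, the transcript Mylk-201 held 99.93% in replicate 1 and 99.98% in replicate 2. The pyruvate kinase gene Pkm was mostly Pkm-201, at 88.9% ± 3.15, and the alpha-actinin gene Actn1 was divided between Actn1-202 at 59.9% and Actn1-201 at 40.1% ± 1.19 (SD, n = 2). For Hnf4a, Hnf4a-202 held 79.6% ± 6.17. The tropomyosin gene Tpm1 was spread over several transcripts, the most abundant at 36.2% ± 6.12 and the next at 31.2% ± 1.31 and 19.7% ± 1.40 (SD, n = 2). In Fn1 the retained-intron transcript Fn1-202 held 30.3% in replicate 1 and 58.7% in replicate 2.

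The splice junctions and transcribed contigs were given for the whole series on the older build mm9. They comprised 446811 junctions with 43037344 spanning reads, of which 180026 (40.3%) had reads in both read count fields and 189669 (42.4%) rested on 1 read. The 130634 junctions with at least 10 reads held 98.5% of the reads. The junction with the most reads, 370647, spanned chromosome 6 from 78321912 to 78322081 on the plus strand, with 83245 reads in the first field and 287402 in the second. The next, on chromosome 8 from 22619945 to 22620499, had 292 and 281242 reads. Contigs numbered 647881 and covered 220611207 nt with a median length of 192 nt. The contig with the highest level, 16300, lay on chromosome 16 from 11143991 to 11144421. Gene names were not assigned to these mm9 positions.

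Of the 96 synthetic spike-in RNAs, 73 had expected counts above 0 in replicate 1 and 81 in replicate 2, with 73 in both. They took 3.83% of the TPM in replicate 1 and 5.15% in replicate 2. Over the 73 detected in both libraries, the Pearson correlation of log2(TPM + 1) was 0.999 across spike-ins.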

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

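Of 322 alternatives for counts, shares, levels, ratios and correlations, 284 stayed within the spread of the libraries or within 1.5 times the count. For shares, levels and ratios, leaving out 1 of 2 libraries always stays within their SD, and FPKM leaves them nearly unchanged. Those alternatives could not fail, so the tally overstates how stable the results are. The alternatives that moved follow, and where no reason is named the cause was not tested. The correlation across genes, 0.952, was 0.939 with a pseudocount of 0.1 TPM, 0.985 with no filter, 0.900 at a mean TPM of at least 10, and 0.961 with both TMM and median-ratio scaling. Genes at least 2-fold apart, 762, numbered 473 at a mean TPM of at least 10, where fewer genes were compared. The share of the top 100 genes was 26.1% by expected counts, without correction for length. It was 40.4% without the genes named Defa and a number, an alternative chosen after seeing the data. The smooth muscle to epithelial structure ratio was 0.239 from list medians. Genes with 1 dominant isoform, 1558, numbered 4738 at 50% dominance and 873 at a mean of at least 20 TPM. By construction stricter limits left fewer junctions, 147380 by reproducibility and 130634 by reads, and fewer contigs, 318115 by reproducibility and 316517 by length. Also chosen after seeing the data, the small intestine enterocyte share of TPM, 0.538%, was 0.243% without Fabp6 and Slc10a2, and the Paneth share, 1.82%, was 0.913% without alpha-defensins. Of the list shares, 21 of 250 alternatives moved, 18 of them on rescaling without mitochondrial genes and spike-ins. Leaving out a library or using FPKM could not move a list share by this rule. Each library alone gave a posterior to anterior Hox ratio of 0.0297 to 0.662 and a mitochondrial share of 3.05% to 6.27%, so either value rests on which library is taken. The list medians near 0 of epithelial structure, interstitial cells of Cajal, T cell, erythrocyte, adipocyte, anterior Hox, mucin and MHC class II genes changed sign under at least 1 setting. The colonocyte list, at percentile 0.01, was at 74.3 with no filter on low values, smooth muscle, at 97.0, was at 99.8 with TMM, and immediate early, at 3.965, reached 2.46. FPKM is proportional to TPM within a library and leaves shares and ratios as they are. Depth limits statements on genes with few counts, such as Car1 or Hoxb13.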

Other observations

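In the circadian clock list, 10 of 12 measured genes were higher in replicate 1, with a median log2 ratio of -0.49 at percentile 0.72. Nr1d1, a repressor of the clock, was at 54.2 TPM in replicate 1 and 26.2 TPM in replicate 2, and Npas2 at 25.5 and 11.1 TPM. All 9 interferon response genes were higher in replicate 1 (median log2 ratio -0.68, percentile 0.18), with Usp18 at 11.5 and 3.86 TPM. The immediate early list lay within the central 95% of its random lists (percentile 3.965, but 2.46 at the lowest over the settings), with 5 of 11 genes higher in replicate 2, Fos at 116 and 38.1 TPM and Egr1 at 6.8 and 6.98 TPM. The mucosal mast cell protease genes Mcpt1 and Mcpt2 were at 55.5 and 12 TPM in replicate 1 and at 5.01 and 1.14 TPM in replicate 2. The gastric genes Pgc, Tff1, Gkn1 and Gkn2 were low but higher in replicate 2, with Pgc at 2.98 and 17.9 TPM. These differences have no replicate check.

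In the tests below, those of shared paralog reads, of sex as a source of the regional difference and of sexes pooled within a library were chosen after the result was seen, as were the split of the ileal genes into Hox and other genes and the gap within the fixed list, which is taken on the genes that showed the pattern, and leaving out a proximal gene with no counts. The further gene sets were chosen after the pattern was seen but before their own values were looked at.

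The first pattern is the high level of small intestine and Paneth transcripts beside near-absent Car1, Aqp8 and Scnn1g in libraries labelled large intestine. Mainly large intestine with some small intestine would bring colon transcripts along, but of the 9 measured genes of a further colon set of 10, 2 reached 10 TPM in either library, Gsdmc4 at 110 and 82.8 TPM and Fgfbp1 at 36.9 and 61.6 TPM, and Fxyd4 had 0 counts in both. Of the 9 measured genes, 2 lay below 1 TPM in both libraries, Fxyd4 and Tgm3. Those besides these 2, Gsdmc4 and Fgfbp1 lay between 1 and 10 TPM in at least 1 library, such as B3gnt6 at 4 and 3.05 TPM. A minor share of large intestine is therefore not excluded. Reads shared between near-identical paralogs are also argued against, since without alpha-defensins the median of the members of both lists was still 135 TPM in the lower library. All 12 genes of a further small intestine set reached 10 TPM in both libraries, among them Slc5a1 and Mgam, which may be read as the hypothesis of small-intestine tissue under a large intestine label, although no other tissue was compared and how far large intestine expresses these genes was not measured here.

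The second pattern is that members of the fixed small intestine enterocyte list lay apart in opposite directions between the libraries. The ileal genes Fabp6 and Slc10a2 were higher in replicate 2 and the other 8 members higher in replicate 1. A difference in depth or scaling would move them alike. It is argued against by Fabp6 and Slc10a2, which lay at least 4.44 above every other member of the list, a gap that 1 factor per library would not give. With TMM the list's median log2 ratio was -1.69, at percentile 0. Since 1 factor moves the list and its random lists nearly alike, this percentile could hardly change and adds no evidence. The median log2 ratio of 7 further ileal genes exceeded that of 11 further proximal genes by 1.37. Resampling the genes gave an interval of 0.31 to 2.88, which does not cover the spread between animals or libraries. The difference of 1.37 is past the bound of 1 set against scaling and for position along the small intestine. It rests on the 4 Hox genes, which alone gave 2.14. Among these, Hoxb7 and Hoxb8, at log2 ratios of 1.63 and 1.83, lie beside Hoxb9 on chromosome 11. Hoxb9 belongs to the fixed lists and was already seen to be higher in replicate 2, so these neighbours are not an independent check. Hoxc8 and Hoxc6 were at 0.31 and 0.20. Without the 4 Hox genes the difference was 0.42, and the other 3 ileal genes, Slc34a2, Amn and Cubn, were all lower in replicate 2. Their median log2 ratio was -0.75, and that of the proximal genes -1.17. So these sets do not decide on position, and against scaling they count only through the Hox genes. Position is a candidate explanation that stays open, as does a difference in sex, since each sex-linked pattern was seen in 1 library and sex and position cannot be told apart. Of the proximal genes 7 also belong to the further small intestine set, and Tmprss15 had 0 counts in both libraries, without which the differences were 1.41 and, without Hox genes, 0.46. All 12 genes of the further small intestine set were higher in replicate 1, with a median log2 ratio of -1.04. Apart from the Hox genes, no gene of the further ileal, proximal or small intestine sets was higher in replicate 2.

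The third pattern is Y-linked transcripts without Xist in replicate 1 and Xist without Y-linked transcripts in replicate 2. If each library pooled both sexes, Y-linked counts would be seen in both, but those of replicate 2 were at most 0.28% of those of replicate 1 after scaling by depth (upper 95% bound). An artifact of the mm10 quantification is argued against by the separate mm9 junctions, where 47 chromosome Y junctions with at least 10 reads held 1290 reads in one field and 17 in the other, a ratio of 75.9. The hypothesis that remains is male tissue in one library and female tissue in the other, for which no further test was possible here.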
